A study of Homo sapiens with 20 samples.

How the data were processed

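The study measured the abundance of guide RNAs by amplicon sequencing of genomic DNA from pooled screens, at day 0 and at day 14 after doxycycline induction of a nuclear RNA-targeting Cas13d nuclease. Its 20 libraries fall into 4 screens, each with its own table of guides. RfxCas13d was induced in HAP1 and in HEK293FT cells that had received the same guide library, with 2 libraries per day. RfxCas13d was induced in A375 cells with another library, which the labels call a dual titration, and HfCas13d, a high-fidelity form, in HAP1 cells with yet another library, each with 3 libraries per day. The labels describe separate infection replicates.

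The unit of every deposited value is signal, since the authors normalised the tables in a way that the labels do not state. The submitters' processing notes name cutadapt 1.13, Bowtie 1.1.2 and the build GRCh38. In the A375 and HfCas13d tables each value less 1 was a whole multiple of a single step per library, within a tolerance of 0.01 of a whole read, for 100% of values in every library, so that reads could be recovered. In the RfxCas13d HAP1 and HEK293FT tables no value repeated within a library and no step existed, so the depth of these libraries is unknown. The recovered depth per library is in the results. In A375 at day 14, 482, 469 and 472 guides lay at the lowest level, and whether that level stands for 1 read or for 0 reads with 1 added was not settled. The size of the fall of guides at that level is therefore uncertain.

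The tables carry guide numbers, a mark for non-targeting guides in 3 of the 4 tables, and no sequences or gene names. Nothing in the files used here pairs a guide with a gene, so the gene-level tests, the 17 gene lists and the named-gene rule that had been fixed before the data were examined could not be run, and guides are given by their numbers. Single guides are named only as the guide with the lowest and the guide with the highest log2 fold change past the threshold, in RfxCas13d HAP1 and in HEK293FT. Values without a guide ID were left out, namely 1 in HAP1, 120 in HEK293FT and 48 in HfCas13d, and 17 repeated IDs in HAP1 and 16 in HEK293FT were averaged. This left 17690, 17572, 6211 and 40070 guides in RfxCas13d HAP1, HEK293FT, A375 and HfCas13d HAP1.

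The tests fixed beforehand were count models. They were replaced in all 4 screens after the unit was known, because the values are normalised signal. In A375 and HfCas13d, where reads could be recovered, voom on those reads was run as an alternative only. Log2 signal was fitted with limma 3.58.1 under R 4.3.3, day 14 against day 0 within each screen, with empirical Bayes variances that follow a trend on the mean. Calls required a Benjamini-Hochberg adjusted p under 0.05. A minimum mean signal of 10 removed 0 guides. Libraries of 3 screens were scaled by the mean of log2 deviations over the non-targeting guides after trimming 30% from each side. The table of A375 has no non-targeting mark, and the plan for that case was a trimmed mean over all guides. This plan was departed from after most guides were seen to fall and the 1372 guides that follow the grids described in the results were seen to have medians between 162.5 and 168.5 in all 6 libraries. The A375 values were therefore used as deposited, and the planned scaling is printed beside them.

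Targeting guides were compared with non-targeting guides by camera with a preset correlation of 0.01 and with an estimated correlation, and each class was tested against no change by fry. The difference between HAP1 and HEK293FT was tested as an interaction of day and cell line over the 17571 guides in both tables. The HfCas13d and RfxCas13d HAP1 tables share 0 guide names, so the nucleases are set side by side without a test of the difference.

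Several units were found by looking at the data and are additions. Guide numbers fall into sets of 4 in the HAP1 and HEK293FT tables and into sets of 8 in the HfCas13d table. Log2 values were averaged per set and library, for sets with at least 75% of their guides, and fitted with limma. In the A375 table consecutive numbers form grids of 11 by 11 places. Grid means and place means per library were fitted with limma, and the corner contrast of a grid was the first plus the last corner less the corners at the ends of row 1 and column 1, which is 0 where rows and columns add. Its exact permutation test was two-sided over the 20 regroupings of the 6 libraries.

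The alternatives were other scalings, a minimum mean of 50, pseudocounts of 1 and 10, a replicate block, replicate numbers crossed between days, other variance priors, an absolute log2 fold change of at least 1, voom on recovered reads, other ways to combine sets, and each library left out in turn. Same-numbered libraries of day 0 and day 14 deviated oppositely from their day's mean in HAP1 (r = -0.439 across guides) and HEK293FT (r = -0.327), which is why the crossed numbers were added. A pairing chosen in this way lowers the residual spread and so favours calls in both directions. In A375 and HfCas13d the same correlation lay between 0.0036 and 0.113. Whether the opposite deviations come from the replicate numbers or from the authors' unstated normalisation cannot be told and was not tested. Pipelines were tested on simulated data made from each screen, with 200 guides changed. In these, limma recovered 62% of 100 guides lowered by 1 on the log2 scale in HAP1 (17690 guides tested), 92% in HEK293FT (17572 tested), 3% in A375 (6211 tested) and 98% in HfCas13d (40070 tested). For falls of 2 it recovered 98%, 97%, 47% and 100% respectively. False calls made up 3.03%, 7.35%, 3.85% and 6.16% of the guide calls of these screens, and 6.40%, 5.74% and 3.85% of the set calls in HAP1, HEK293FT and HfCas13d. The simulated noise was normal, independent between libraries and guides, and drawn from the fitted variances, so these rates hold for such noise only. Of real non-targeting guides, 104 of 999 in HAP1 and 151 of 1000 in HEK293FT had an unadjusted limma p under 0.05. In A375, where 51.2% of guides fell, recovery with 200 changed guides is unlike the real fit. Computation also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.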

Results

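The data were guide abundances in 20 libraries of 4 pooled screens. HAP1 is a near-haploid line from a chronic myelogenous leukaemia, HEK293FT a line from embryonic kidney, and A375 a melanoma line. RfxCas13d HAP1 and HEK293FT had 2 libraries at day 0 and 2 at day 14 each. RfxCas13d A375 and HfCas13d HAP1 had 3 at each day. Recovered reads per library in A375 were 1342178, 868384 and 1684142 at day 0 and 746951, 873999 and 494672 at day 14. In HfCas13d they were 7196215, 7755380 and 9122431 at day 0 and 6987973, 8313186 and 14338227 at day 14. The depth of the RfxCas13d HAP1 and HEK293FT libraries is unknown. Guide names could not be paired with genes.

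The first comparison asked which guides were lost over 14 days of RfxCas13d in HAP1 cells. Of 17690 guides, 1154 fell and 151 rose. The median fall among the lower guides was -1.87 on the log2 scale, and 598 targeting guides lay below -2. The loss was carried by a tail of the 16691 targeting guides, whose median was 0.02 and whose mean was -0.13. With a replicate block 81 guides rose, with the replicate numbers crossed between days in that block 2005 fell and 1295 rose, and with a library left out between 79 and 395 rose. Among 999 non-targeting guides 4 fell and 4 rose, and 104 had an unadjusted p under 0.05, more than the share of 0.05 that chance gives. The share of targeting guides below the lowest 1% of non-targeting guides was 9.42%. Non-targeting guides were more abundant, with a median signal of 430.5 against 108.3 for targeting guides in the first day 0 library, so their narrower spread is not a like-for-like floor.

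The guide gID_04020 fell most, with a log2 fold change of -7.68 ± 0.97 (SE, n = 2 per day) and an adjusted p of 0.00101 from limma. Its mean signal at day 14 was 1.05, near the lowest of these libraries, so the size of its fall rests on how low values are treated: it was -6.72 with a pseudocount of 1 and -4.35 with a pseudocount of 10. With a minimum mean signal of 50 its adjusted p was 0.0774. The guide gID_08089 rose most, with a log2 fold change of 2.53 ± 0.22 (SE, n = 2 per day) and an adjusted p of 7.37e-05 from limma. The difference between targeting and non-targeting guides as classes did not pass the threshold by camera (p = 0.559), nor with an estimated correlation (p = 0.57). By fry, which tests a class against no change, p was 0.11 for targeting and 0.646 for non-targeting guides. The scaling holds the non-targeting guides near 0 on average, so their p is no independent result.

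Neighbouring guide numbers changed alike within sets of 4. The correlation across guides, which are not independent replicates, was 0.914 between neighbours of a set and 0.169 across set borders. Both values may be shaped by the order of HAP1 changes within sets that is described below. Of 4175 sets, 507 fell and 118 rose, and 1 of 250 sets made of non-targeting guides was called. The rising sets numbered between 37 and 229 with a library left out, 67 with a replicate block and 246 with total signal scaling. In 79 of the 507 lower sets all 4 guides were called lower, in 110 sets 3 guides, in 146 sets 2, in 125 sets 1 and in 47 sets none. The median change of the lower sets was -1.10. With the replicate numbers crossed between days in a block, 689 sets fell and 591 rose. Borders moved by 1, 2 or 3 numbers gave 568, 532 and 514 lower sets and 63, 34 and 43 higher sets, so groupings across the borders called at least as many sets lower and fewer higher. In 78.8% of 4162 complete sets the HAP1 fold change fell fully along the numbers, against 4.17% by chance and 5.00% of sets in HEK293FT. How the sets were formed is not documented, and sets formed with knowledge of the HAP1 outcome would bias the HAP1 set counts.

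**Figure D1:**
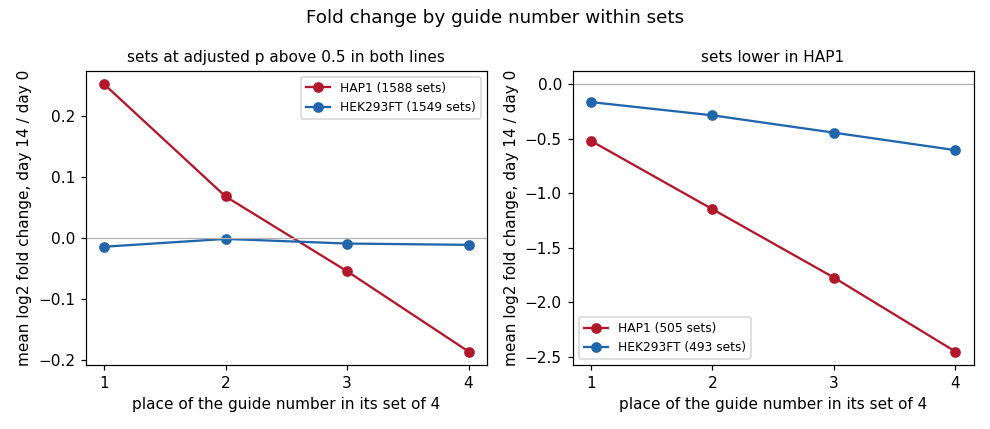
Mean log2 fold change, day 14 over day 0, by place of the guide number in its set of 4, for sets with an adjusted p above 0.5 in both lines and for sets lower in HAP1. HAP1 means fall along the places in both kinds of set, and HEK293FT means go from -0.16 to -0.61 in the sets lower in HAP1.

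The same library in HEK293FT cells lost fewer guides past the threshold. Of 17572 guides, 209 fell, with a median of -1.55, and 3 rose. Of 1000 non-targeting guides 0 were called by limma, and 151 had an unadjusted p under 0.05, a share above the 0.05 that chance gives, so that the unadjusted p of this screen runs low. The share of targeting guides below the lowest 1% of non-targeting guides was 2.75%. The non-targeting guides had tails of their own, from -2.33 to 1.83, with 2 guides below -1. Only 57 targeting guides (0.34%) lay below the lowest of them. Non-targeting guides were also more abundant here, with a median signal of 433.9 against 134.5 in the first day 0 library. The guide gID_14012 fell most, with a log2 fold change of -5.48 ± 0.75 (SE, n = 2 per day) and an adjusted p of 0.00823 from limma, which a robust variance prior moved to 0.269. Its change was -3.96 without day 14 replicate 1, -6.99 without day 14 replicate 2 and -4.31 with a pseudocount of 10. The guide gID_15306 was the highest of the called guides at 0.78 ± 0.13 (SE, n = 2 per day) with an adjusted p of 0.0298, or 0.0885 with a replicate block. Of 4174 sets, 127 fell and 1 rose, and borders moved by 1, 2 or 3 numbers gave 191, 153 and 173 lower sets. Neighbours correlated at 0.434 within sets and 0.063 across borders, over guides. The class test gave p = 0.0504 by camera and p = 0.165 with an estimated correlation, and 0.0417 with a replicate block. With the replicate numbers crossed between days in a block, 674 guides fell and 146 rose, and 287 sets fell and 19 rose. With a library left out, between 209 and 445 guides fell and between 6 and 44 rose. The lower sets numbered 65 without day 0 replicate 2, 68 without day 0 replicate 1 and 332 without day 14 replicate 2, and 207 with a replicate block.

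**Figure D2:**
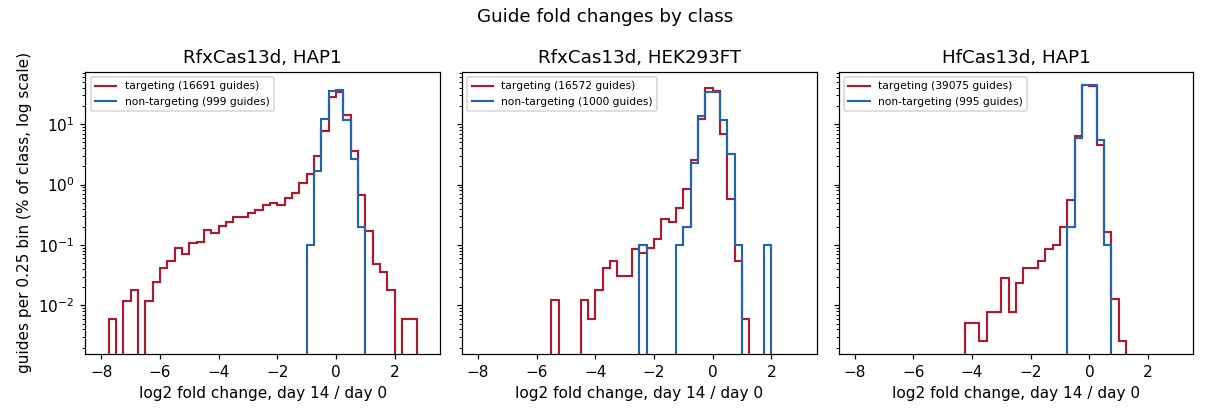
Distribution of log2 fold changes, day 14 over day 0, as percent of guides per bin on a log axis, for targeting and non-targeting guides in 3 screens. The targeting guides have a tail of losses that reaches -7.68 in RfxCas13d HAP1, -5.48 in HEK293FT and -4.17 in HfCas13d HAP1. In HEK293FT the non-targeting guides reach -2.33.

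The next comparison asked whether the change from day 0 to day 14 differed between HAP1 and HEK293FT. It did for 825 of 17571 guides, of which 696 were lower in HAP1 and 129 lower in HEK293FT. A change lower in HEK293FT need not be a loss there, since guides that rose in HAP1 count on that side too. Within the lines, 43 targeting guides were called lower in HEK293FT only, and 146 were called higher in HAP1. Of 4174 sets, 346 were lower in HAP1 and 98 lower in HEK293FT. In both lines 105 sets fell, against 15.4 that independence would give. These were 82.7% of the sets lower in HEK293FT and 20.7% of those lower in HAP1, where 402 sets were called in HAP1 alone. Among the 507 sets lower in HAP1 the median change was -1.10 in HAP1 and -0.21 in HEK293FT, and 89.3% of them were below 0 in HEK293FT.

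Of the guides named above, gID_04020 was at -4.08 in HEK293FT, a difference of -3.60 ± 0.59 (SE) with an adjusted p of 0.0032 from limma, which shrank to -0.80 with an adjusted p of 0.182 with a pseudocount of 10. The guide gID_08089 was at -0.55 in HEK293FT, a difference of 3.07 ± 0.32 (SE) with an adjusted p of 0.000171. Both were chosen as extremes in HAP1, which favours a difference in that direction. The guide gID_14012 was at -5.61 in HAP1 and did not pass the test of the difference. With a library left out, the guides lower in HAP1 numbered between 376 and 880. A replicate block lowered the guides lower in HEK293FT from 129 to 39 and the sets from 98 to 28. It left 283 sets lower in HAP1. Crossed numbers gave 1289 and 845 guides and 512 and 509 sets lower in HAP1 and in HEK293FT. That pairing was chosen after the opposite deviations were seen and favours calls in both directions. It therefore cannot tell whether the excess of sets in HAP1 depends on how replicates are paired. Each line has its own table, normalised by the authors in a way not stated, so line and table cannot be separated.

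**Figure D3:**
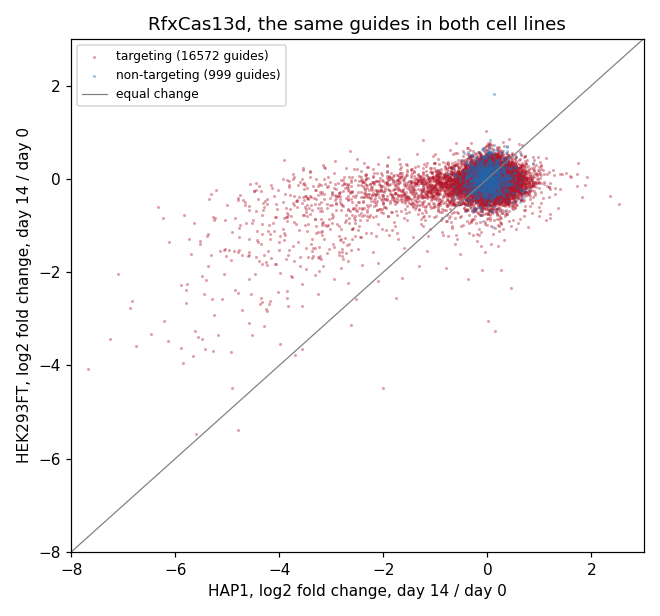
Log2 fold change of each guide in HAP1 (x axis) and HEK293FT (y axis), with 1 point per guide and the line of equal change. By the test of the difference the change was lower in HAP1 for 696 guides and lower in HEK293FT for 129.

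The A375 screen was called a dual titration in the labels, which do not say what was titrated. On the deposited scale 3181 of 6211 guides (51.2%) fell, with a median of -3.68, and 101 rose. The rising guides numbered between 43 and 143 with a library left out and 413 with upper-quartile scaling. With the planned trimmed mean over all guides 2149 fell and 2412 rose, a scaling whose day 14 factors lay -1.41 on the log2 scale from those of day 0 and which raises every fold change by as much, so the balance between falling and rising guides rests on the scaling. In 886 guides at least 1 day 14 library, and in 128 all 3, lay at the lowest level, and the size of their falls is uncertain.

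The losses were ordered along the guide numbers in 39 grids of 11 rows by 11 columns, with 4719 guides. A further 120 guides, in a grid short of its full size, came next and were left out of the grid results. Mean log2 fold change went from -0.49 in row 1 to -3.71 in row 11 and from -0.15 in column 1 to -3.98 in column 11. The first corner was at 0.13, the end of row 1 at -1.69, the end of column 1 at -0.35 and the last corner at -5.37. The sum of the edges would give -2.17 for the last corner. The corner contrast was -3.19 and was negative in 38 of 39 grids. It was -1.82 with a pseudocount of 10 and -1.42 over the second and last but one rows and columns. Per library it was -3.21 ± 0.20 (SD, n = 3) at day 14 and -0.02 ± 0.06 (SD, n = 3) at day 0, with a two-sided exact permutation p of 0.1, the smallest that 20 regroupings allow.

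By limma 38 of 39 grid means and 113 of 121 place means fell, and the rest did not pass the threshold. With the planned trimmed mean 30 grid means and 85 place means fell, and with total signal 33 and 98. Rising means were not counted under these scalings, so the rest cannot be read as unchanged. The planned day 14 factors lay -1.41 on the log2 scale from those of day 0, which raises every mean. Means near 0 on the deposited scale therefore lie above 0 under it. The grid means ranged from -4.05 to -0.07 on the deposited scale. After the mean of each place and of each grid was removed, grids 20 apart in order correlated across places with a mean of 0.681 in 19 pairs, and in 19 of 19 pairs the later grid was the best match of the earlier one, and in 18 the earlier was that of the later. Other pairs reached up to 0.718. The 1372 guides after the grids had a median of 0.03, and 73 of them fell and 47 rose. The deposited scale was kept because the medians of these guides were stable, so a median near 0 follows from that choice.

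**Figure D4:**
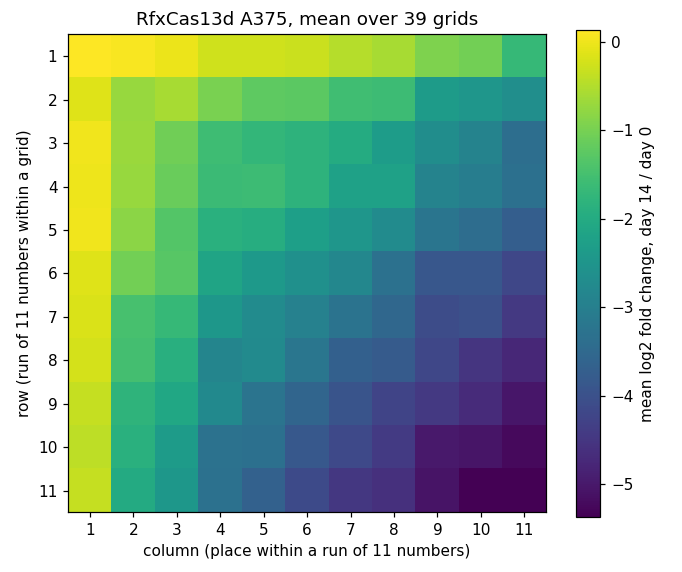
Mean log2 fold change, day 14 over day 0, at each of the 121 places of the grids in RfxCas13d A375, averaged over 39 grids. Values go from 0.13 in the first corner to -5.37 in the last, while the mean of column 1 is -0.15.

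The last comparison asked which guides were lost with HfCas13d in HAP1. Of 40070 guides, 285 fell, with a median of -1.11, and 25 rose. The rising guides numbered between 11 and 58 with a library left out and 53 with a replicate block. Of 995 non-targeting guides 0 were called by limma, and 41 had an unadjusted p under 0.05. Only 159 targeting guides lay below -1. The share of targeting guides below the lowest 1% of non-targeting guides was 2.52%, and 9.42% with RfxCas13d in the same cell line. The libraries differ and share 0 guide names, so this difference between nucleases was not tested. Nor is the floor alike, since non-targeting guides were more abundant than targeting guides with RfxCas13d and of like abundance with HfCas13d (a median signal of 197.4 against 223.7 in the first day 0 library). The class test gave p = 0.4 by camera and p = 0.423 with an estimated correlation.

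Of 4890 sets of 8, 179 fell, with a median of -0.31, and 33 rose. Of the 179, 42 had no guide called lower, 70 had 1 and 0 had all 8. With an absolute change of at least 1 required, 6 sets fell, and without day 0 replicate 3, 19 sets rose. Moved borders gave between 141 and 165 lower and between 9 and 22 higher sets. Neighbours correlated at 0.172 within sets and 0.0234 across borders, over guides. The losses were more frequent at high guide numbers, with a border chosen after seeing the values. Up to number 30000, 66 of 29968 guides and 64 of 3750 sets fell. Past it, 219 of 9107 guides and 115 of 1140 sets fell. What separates these number ranges is not given in the tables.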

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

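The test of the difference between the lines was planned for genes and run on guides, and all other tests in this part were chosen after the result was seen. The change from day 0 to day 14 differed between HAP1 and HEK293FT, by the test of the difference, for 696 guides lower in HAP1 and 129 lower in HEK293FT. It also differed for 346 sets lower in HAP1 and 98 lower in HEK293FT. The set counts moved with each library left out in turn. A replicate block gave 283 sets lower in HAP1 and 28 lower in HEK293FT. With replicate numbers crossed between days as a block the sets numbered 512 and 509. The crossed pairing was chosen from these data and favours calls. It therefore cannot tell whether the excess of sets in HAP1 depends on the pairing. The guides gID_04020 and gID_08089 differed by -3.60 and 3.07 on the log2 scale, but both were chosen as extremes in HAP1, which builds in the direction, and the former was at -0.80 with a pseudocount of 10.

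More guides and sets fell in HAP1 than in HEK293FT. Spread between libraries that non-targeting guides share is argued against, since targeting guides of like abundance were called in 4.48% of cases (67 of 1494) and non-targeting guides in 0.501% (5 of 999). A single common factor, in the sense of a fixed proportion between the changes of the lines, is argued against as the whole cause. Over the 507 sets lower in HAP1, a slope taken across pairs of libraries was removed from the HEK293FT change. What it left correlated at 0.670 (Spearman's rho 0.471) between separate pairs. A common factor with a curved relation could also leave such a correlation, so the test cannot exclude it. The form with the slope of the 529 sets lower in either line, mostly chosen by their fall in HAP1, gave 0.695. The form with a line on the mean HAP1 change, which shares noise, gave 0.766. A factor may still account for much of the difference, since only 5 sets were further lower in HAP1 and 34 in HEK293FT after division by a common slope of 0.289, a step that also multiplies the spread in HEK293FT by 3.45. Spread that acts on targeting guides alone, a difference between the cell lines, a difference in nuclease activity and the authors' separate normalisation stay open and were not tested.

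In A375 the last corner of the grids lay below the sum of its edges. The contrast was -3.19, and it was -1.82 with a pseudocount of 10 and -1.42 over the second and last but one rows and columns. Numbering of rows exactly by their mean fold change in each grid is argued against, since 0 of 39 grids had row means that fell fully from first to last. Column means fell fully in 0 grids too. Looser numbering by outcome stays open, since row means and column means each followed their order with a median rank correlation of -0.9. A product of a row value and a column value left less unexplained than a sum in 31 of 39 grids, which largely restates the corner contrast. No biological explanation was tested, since the tables do not say what the axes are.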

How the results depend on the processing

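The sets, grids, pseudocounts, crossed pairing, variance priors and voom were chosen after seeing the data. No named guide's fold change and no corner contrast changed sign in the alternatives run. The difference of gID_14012 between the lines, not past the threshold, went from -0.13 to 0.15 with a pseudocount of 10, and in A375 the planned trimmed mean turned the balance of calls from falling to rising guides. Without a filter the values were identical, since the filter removed 0 guides. The gene-level results, gene lists and nuclease interaction were not run, since the guides carry no gene or shared names. The planned count models were not run, since the values are signal. In A375 and HfCas13d, where reads could be recovered, voom was run on them as an alternative. It gave 3143 lower and 95 higher guides in A375 and 276 and 20 in HfCas13d. The cause of each change below was not tested, except that a threshold of 1 keeps fewer guides by construction. The depth of the RfxCas13d HAP1 and HEK293FT libraries is unknown, and the lowest read level limits what is known of the largest falls in A375. In A375 the trimmed mean over all guides gave 2149 lower and 2412 higher guides, upper-quartile scaling 413, total signal 1137 and a prior without trend 60. A replicate block gave 81 higher guides and 67 higher sets in HAP1, 0 higher guides, 207 lower sets and a class p of 0.0417 by camera in HEK293FT, 53 higher guides in HfCas13d, and 39 guides and 28 sets lower in HEK293FT than in HAP1. Crossed replicate pairing, a block with the numbers exchanged between days, gave 2005 lower and 1295 higher guides and 591 higher sets in HAP1, 674 lower and 146 higher guides and 287 lower and 19 higher sets in HEK293FT, and between the lines 1289 guides lower in HAP1 and 845 guides and 509 sets lower in HEK293FT, against 512 sets lower in HAP1. A fold change of at least 1 left 40 higher guides, 266 lower and 6 higher sets in HAP1, 0 higher guides and 44 lower and 0 higher sets in HEK293FT, and 159 lower and 1 higher guides and 6 lower and 0 higher sets in HfCas13d. A prior without trend gave 97 higher guides and 53 higher sets in HAP1, 1 higher guide in HEK293FT and 15 in HfCas13d. A robust prior gave 5 higher guides in HEK293FT. The trimmed mean over all guides gave 6 higher guides in HEK293FT, and total signal 9 higher guides and 5 higher sets there and 246 higher sets in HAP1. In HEK293FT summed signal gave 0 higher sets, and sets without the most abundant guide 10. The corner contrast was -2.89 and -1.82 with pseudocounts of 1 and 10, -2.39 in the grids without corners at the lowest level, which the fall itself selects, and -1.42 over the second and last but one rows and columns.

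With each library left out in turn, higher guides ranged from 79 to 395 in HAP1, 6 to 44 in HEK293FT, 43 to 143 in A375 and 11 to 58 in HfCas13d. Lower guides in HEK293FT ranged from 209 to 445, the highest without day 14 replicate 2, and its camera p from 0.0277 to 0.146. Higher sets ranged from 37 to 229 in HAP1, 0 to 11 in HEK293FT and 19 to 36 in HfCas13d, and lower sets in HEK293FT from 65 (without day 0 replicate 2) to 332 (without day 14 replicate 2). Between the lines, guides lower in HAP1 ranged from 376 (without HEK293FT day 0 replicate 1) to 880 and sets from 214 to 373. Guides lower in HEK293FT ranged from 52 to 280 and sets from 28 to 178, both highest without HAP1 day 14 replicate 2. A fit that leaves 1 library on a day assumes that it varies like the others.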

Other observations

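The tests of the guide order and the splits were chosen after the result was seen, while the guide counts that the splits refer to were planned. In HAP1 the fold change fell along the guide numbers within sets of 4, fully so in 78.8% of 4162 sets against 4.17% by chance. The order was also there in 75.4% of the 1588 sets with an adjusted p above 0.5 in both lines, while in HEK293FT such sets fell fully in 3.03% of cases, a gap of 72.4 points. A strength fixed before the screen is argued against as the whole cause, and the numbers may have been given after the HAP1 outcome was known. In the sets lower in HAP1, HEK293FT means by place were -0.16, -0.29, -0.45 and -0.61, so part of the HAP1 order carried over to the other line. No biological explanation of the order was tested. The correlations between neighbours in HAP1, 0.914 within sets and 0.169 across borders, may rest in part on the order. Such an order places like values side by side within a set, and the low end of a set beside the high end of the next. Its share in these correlations was not tested.

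The splits of the 6 libraries into groups of 3 are too few for a share under 0.05, since 1 of 10 splits is the real one. In A375 the real split gave 3181 lower guides and the highest other 2, 101 higher guides and 0, and 38 lower grid means and 0. In HfCas13d it gave 285 lower and 25 higher guides and 179 lower and 33 higher sets, and every other split gave 0.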
